A study of Mus musculus with 8 samples.

How the data were processed

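Total RNA from the dorsal skin of mouse embryos at embryonic day 18.5 was measured on 8 arrays, 4 from embryos lacking corneodesmosin in the epidermis (KO, keratin 14-driven Cre with floxed Cdsn alleles) and 4 from control embryos with the same Cre and unfloxed Cdsn alleles (WT). Each array came from a separate embryo; the labels do not give litters or sexes, so p-values measure the spread between these embryos. Per the labels' protocols, the skin was tape-stripped, kept on culture medium for 4 h at 37 °C, held in an RNA-preserving solution for up to 4 weeks and extracted on RNeasy columns, and biotin-labelled targets were made from 9 µg of RNA.

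The deposited series values are log2 intensities, 1 per probe set and array, for 33793 probe sets. The submitters' processing notes name RMA, a method that corrects, scales and summarises the probes of each probe set on the log2 scale; its role and version, and whether it was run on all 8 arrays together with quantile normalization, are not given in the sources used here. Per the file headers, the array was the Affymetrix Gene Mouse 2.0 ST, which reads each gene with several short probes spread along its transcripts. The authors' deposited table holds, per the file headers, the mean log2 intensity of each genotype, the fold change as a linear ratio (KO over WT), its log2 value, a p-value and a Benjamini-Hochberg adjusted p-value for 5460 probe sets chosen by an adjusted p under 0.05 and a log2 change over 0.5 in size. It also gives each probe set's probe count and an annotation class score as deposited, 1 or 3; in Affymetrix's scheme these stand for unique and mixed probe sets, a meaning the table itself does not state. The genome build is not given in the sources used here, so chromosomes are given without coordinates. No background or detection value and no array scan date were used here, and the number of arrays, not sequencing depth, limits the precision.

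The values were used as deposited, with no further scaling, in limma 3.58.1 (R 4.3.3; lmFit and eBayes, no covariate), KO minus WT, with Benjamini-Hochberg adjustment over all 33793 probe sets and a threshold of 0.05. Every adjusted p of a gene below comes from this fit unless another setting is named. It returned all 5460 probe sets of the authors' deposited table at their criteria, with log10 p-values that differed by at most 3.62e-08. The fit was planned on probe sets with exactly 1 gene symbol and 1 probe set per gene. Gene names were given only for the 5460 probe sets of the authors' table, so all probe sets were fitted instead. Of these 5460, 5161 carried a symbol and 299 did not. The accessions of 3411 matched RefSeq (the GRCm38.p6 table), 227 of them under another symbol; the authors' symbol is printed. The symbols stand for 5079 genes, of which 60 had several probe sets and 7 had probe sets that disagreed in direction; the probe set with the highest mean over the 8 arrays stood for each gene.

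A set of 35 gene lists was fixed before the data were examined: cornified envelope and late differentiation; desmosome and corneodesmosome; tight and adherens junction; epidermal proteases and inhibitors; barrier lipids; cholesterol biosynthesis; wound and stress keratinocyte genes; antimicrobial peptides; inflammatory cytokines and chemokines; the type 2 cytokine axis; NF-kB feedback; immediate early genes; EGFR ligands; NRF2 targets; interferon response; heat shock and unfolded protein response; hypoxia and glycolysis; cell cycle; basal keratinocyte; hair follicle; fibroblast; adipocyte; muscle; endothelium; neutrophil; macrophage and dendritic cell; mast cell; T cell; melanocyte; nerve; erythroid; Y-linked and Xist; WNT, BMP and SHH; circadian clock; and glucocorticoid, vitamin D and calcium response. Unchanged members could not be named, so the planned camera test, and a count adjusted over the list alone, could not be made. Instead, the share of rises among a list's named genes was set against that among all other named genes with a two-sided Fisher's exact test (SciPy 1.17.1), Benjamini-Hochberg adjusted over the 21 lists with at least 5 named members. This test, chosen after seeing which names were given, asks only about direction among changed genes, and treats genes as independent, which they are not. A list member not named in the authors' table did not meet their criteria, was not measured, or could be among the 299 probe sets without a symbol.

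The genes named were set by a rule fixed with the lists: Cdsn; the 10 largest rises and the 10 largest falls past the threshold with no overlap between the 4 KO and 4 WT values, leaving out symbols of the patterns used for predicted, unnamed and RNA genes and olfactory and vomeronasal receptors; and up to 4 members of each list with the largest changes. Where a list had none past the threshold, its 2 members with the highest mean were to be named; this applied to Y-linked and Xist, whose probe sets could not be named, so the planned check of embryo sex could not be made; the changed probe sets on chromosome Y are given with the results. The exclusion went by symbol alone, so U90926 and Sprr2g, whose probe sets carry accessions of non-coding RNA, were kept. Some genes that meet this rule are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

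Alternatives were median centring of the arrays, quantile and cyclic loess normalization, a filter on low probe sets, counting identical probe sets singly, an intensity trend with robust eBayes, no moderation, array weights, the replicate number as a block, leaving out each array, leaving out both arrays that stood apart, leaving out the Lce1 genes from the list tests, and other thresholds. On data simulated for KO against WT from the WT means and each probe set's own spread (33793 probe sets, 50 changed per size), limma recovered 92% of log2 changes of 2, 76% of 1 and 10% of 0.5, and 68% of falls of −1, with 6 unchanged probe sets called. Far fewer probe sets were changed there than were called in the data, and the noise was independent between probe sets. These rates therefore need not hold for the data. The direction test called 3.2% of 1000 random lists of 28 named genes.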

Results

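Gene expression was measured in the dorsal skin of mouse embryos that lacked corneodesmosin in the epidermis (KO, 4 embryos) and of control embryos (WT, 4 embryos). Corneodesmosin, the product of Cdsn, is an adhesive protein of the corneodesmosomes that hold the cells of the stratum corneum together. All skins had been tape-stripped and cultured for 4 h, so the comparison asks how stripped skin without corneodesmosin differed from stripped control skin. Median log2 intensities were 4.81 to 4.88 on the KO arrays and 4.70 to 4.80 on the WT arrays. Correlations across probe sets, which are not independent replicates, were 0.979 to 0.989 within a genotype and 0.967 to 0.980 between genotypes, and no arrays were duplicates. The first principal component held 43.6% of the variance and placed the KO arrays between −46.0 and −25.4 and the WT arrays between 34.8 and 43.7. KO replicate 3 lay nearest to the WT arrays on it, and WT replicate 1 stood apart on the second component at −51.3.

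Cdsn, on chromosome 17, was at 0.0906 times its WT level in KO skin. Its log2 intensity was 8.38 ± 0.42 (SD, n = 4) in KO and 11.84 ± 0.18 (SD, n = 4) in WT skin, a change of −3.46 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 0.000125). All 4 KO values lay below all 4 WT values, and the exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. The labels do not say which part of the gene was floxed, so which probes lie inside the deleted part is unknown here.

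Single genes that were higher in KO skin included chemokines, cytokines, epidermal growth factor receptor (EGFR) ligands and wound-response genes, and those that were lower included the Lce1 genes of the cornified envelope. Of 19 alternatives, the tests of these groups, given below, were lost in 1 for the envelope list, with the Lce1 genes left out, in 7 for the cytokine list and in 10 for the wound list, while the EGFR list had too few named genes to test. Among genes with symbols of named genes and no overlap between the groups, the largest rise was that of Cxcl5, a chemokine that attracts neutrophils, which was 17.8-fold higher (log2 change 4.15 ± 0.39, SE; KO 7.70 ± 0.98 and WT 3.55 ± 0.17, SD, n = 4 each). Il1b, an inflammatory cytokine, rose by 2.97 ± 0.28 (SE) on the log2 scale, and the small proline-rich gene Sprr2g by 2.89 ± 0.60. Fgf23, a hormone known for its control of phosphate, rose by 2.88 ± 0.39, and the EGFR ligand Epgn by 2.59 ± 0.53. The 10 largest rises also held U90926 (2.65), Lce3d (2.57), the matrix metalloproteinase Mmp3 (2.52) and the prostaglandin synthase Ptgs2 (2.49). After Cdsn, the largest falls were those of Lce1e (−2.85 ± 0.33), Lce1a2 (−2.63 ± 0.18), Lce1k (−2.28 ± 0.24) and Lce1l (−2.22 ± 0.31). Lce1d (−2.18), Lce1a1 (−2.16), the flavin monooxygenase Fmo2 (−2.16), Lce6a (−2.06) and Lce1b (−2.02) completed the 10 largest falls. In each of these genes the 4 KO values did not overlap the 4 WT values. Sprr2g and Epgn missed the threshold without variance moderation (adjusted p = 0.0604 and 0.057 in limma without eBayes), and were among 46 of the 121 genes set by the naming rule besides Cdsn that did so.

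Of 33793 probe sets, 7194 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 5138 higher and 2056 lower in KO skin, so that 71.4% were rises. The KO arrays were slightly brighter, and the share of rises depended on the scaling. Centring each array on its median gave 2965 higher and 3075 lower (49.1% rises), quantile normalization 3229 and 3169 (50.5%), and cyclic loess 3227 and 3165 (50.5%). The median change of all probe sets was 0.09 as deposited and −0.02 after centring. Groups did not overlap in 25.0% of all probe sets, where chance gives 2.86%. Of the genes with a name, 3760 rose and 1319 fell.

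Of the 50 genes of the cornified envelope list, 29 were named among the changed genes, 9 of them higher and 20 lower, against 74.3% rises among the other named genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.97e-05). The call rested on the Lce1 genes: without them, a setting chosen after the values were seen, 9 rose and 6 fell (adjusted p = 0.58, same exact test). All 14 Lce1 genes, which encode late cornified envelope proteins, fell, by −1.38 to −2.85 with a median of −1.97, while all 6 Lce3 genes, known to be induced in injured skin, rose by 0.84 to 2.57. In a test of gene families chosen after the values were seen, the direction of the Lce3 genes did not pass (adjusted p = 0.493, same exact test). Lce3b and Lce3f missed the threshold after centring (limma adjusted p = 0.0508 and 0.0515). In all, Lce3f missed it in 11 alternatives, Lce3b in 10, Lce3c in 6, Lce3a in 4 and Lor in 3. Further members, chosen after their values were seen, were the filaggrin gene Flg (−0.57 ± 0.12, SE), the loricrin gene Lor (−0.53 ± 0.14) and Flg2 (−0.95 ± 0.12), which fell less, and Sprr1a (1.28 ± 0.29), which rose. Chosen in the same way, Hrnr (−0.72 ± 0.12) and Krt78 (−0.66 ± 0.13) fell, as did Lce6a. Sprr4 (0.70 ± 0.20) and Tchhl1 (0.65 ± 0.18) rose as deposited but missed the threshold after centring (limma adjusted p = 0.0547 and 0.0567). The rises outside the Lce1 genes were thus the Lce3 genes, Sprr1a, Sprr4 and Tchhl1. The Lce and Sprr2 genes form families of close copies whose probes may bind each other's transcripts, which was not measured, so the values of single members are uncertain. The other 21 members of the list were not named in the authors' deposited table.

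**Figure D1:**
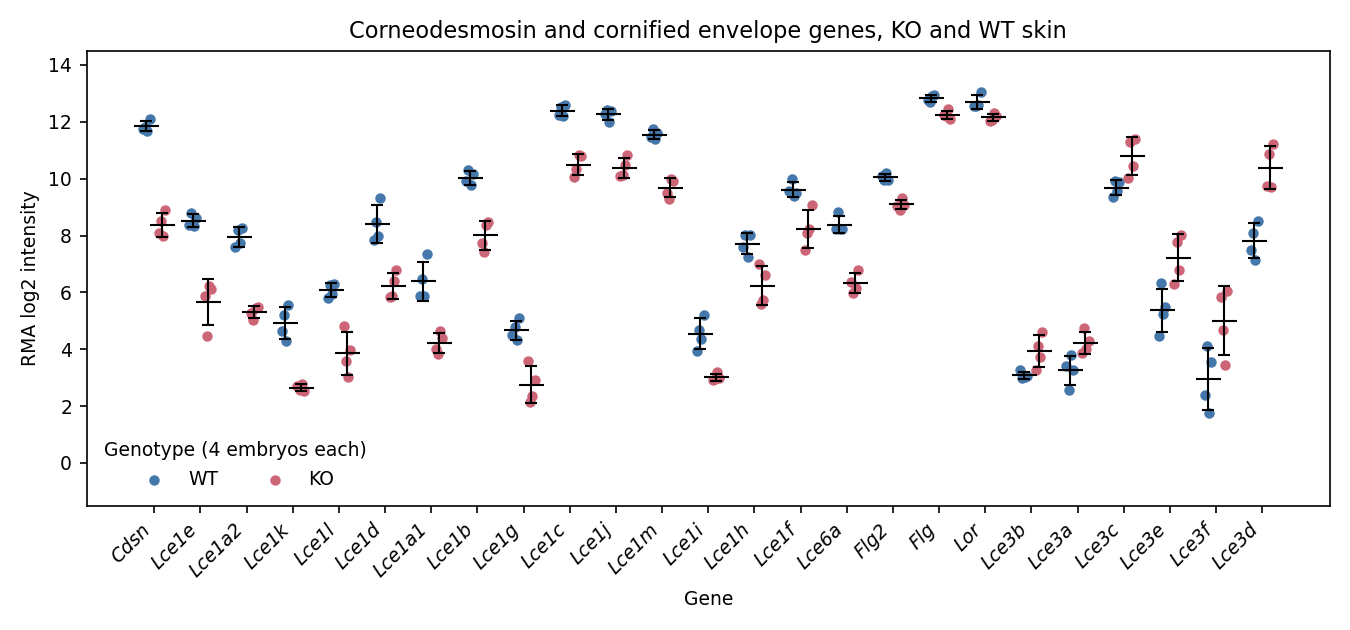
RMA log2 intensity (y axis) of Cdsn and cornified envelope genes (x axis) in each of 4 WT and 4 KO embryos, with points for embryos and bars for the mean ± SD. The 14 Lce1 genes lie lower in KO skin, by a median of −1.97, and the 6 Lce3 genes lie higher, by 0.84 to 2.57.

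The other barrier lists had no direction that set them apart from other named genes, or too few named members to test. In the desmosome list 3 of 19 genes were named: Cdsn, the plakophilin gene Pkp2 (1.28 ± 0.29, SE) and the desmoglein gene Dsg4 (1.07 ± 0.23). Among 23 junction genes 7 rose and 1 fell (adjusted p = 0.779, Fisher's exact test), with the claudin genes Cldn4 (1.39 ± 0.19) and Cldn6 (0.92 ± 0.19) in front. All 6 named protease and inhibitor genes of 37 rose (adjusted p = 0.611, same exact test), among them the inhibitors Slpi (2.04 ± 0.43) and Serpinb2 (1.57 ± 0.25). Of 42 barrier lipid genes 5 rose and 4 fell (adjusted p = 0.585, same exact test). The sphingomyelin synthase Sgms2 rose (1.80 ± 0.33), and the sphingomyelinase Smpd3 (−1.25 ± 0.18) and the phospholipase Plb1 (−1.23 ± 0.22) fell. Of 25 cholesterol genes 4 rose and 1 fell (adjusted p = 1.0, same exact test), the last being the reductase Dhcr7 (−0.64 ± 0.14), and 2 of these 5 passed after centring.

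Of 46 cytokine and chemokine genes 28 were named, 27 higher and 1 lower (adjusted p = 0.0279, Fisher's exact test), and 25 of them passed after centring. Besides Cxcl5, Il1b and Ptgs2, Cxcl3 rose by 2.43 ± 0.33 (SE). Others, chosen after their values were seen, were Ccl20 (2.40 ± 0.38), Ccl2 (2.33 ± 0.28), Il24 (2.24 ± 0.46), Il6 (2.14 ± 0.36) and Lif (2.06 ± 0.27), and the gene that fell was Il18 (−0.79 ± 0.20), which missed the threshold in 3 alternatives. The lists of immune cell markers held rises alone among their named genes, but their share of rises did not pass the test against other named genes. All 14 named macrophage and dendritic cell genes of 23 rose (adjusted p = 0.117, Fisher's exact test), by 0.53 to 1.06, with Cd74 (1.06 ± 0.16) and Cd14 (1.01 ± 0.22) in front, and 12 passed after centring. All 9 named T cell genes of 18 rose (adjusted p = 0.37, same exact test), led by Tcrg-V5 (1.21 ± 0.16). The mean level of Tcrg-V5 was 4.52 in KO and 3.31 in WT skin, below the median level of all probe sets, 4.76. All 5 named neutrophil genes of 19 rose (adjusted p = 0.611, same exact test), among them Trem1 (1.16 ± 0.23). After centring, 8 of the T cell genes and 3 of the neutrophil genes passed. The cytokine list's call was lost without KO replicate 1 (adjusted p = 0.117, exact test) and without WT replicates 1, 2, 3 or 4 (0.0893, 0.0941, 0.144 and 0.064, exact tests). It was also lost with low probe sets left out (0.249) and without both arrays that stood apart (0.0576), both by the exact test.

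In the wound and stress keratinocyte list 21 of 43 genes were named and all 21 rose (adjusted p = 0.0244, Fisher's exact test), 16 of them past the threshold after centring. After Sprr2g and Mmp3 the largest were Sprr2i (2.44 ± 0.63, SE) and Gm5416 (2.14 ± 0.54). The matrix gene Tnc (2.02 ± 0.29) and the stress keratin Krt6a (1.70 ± 0.53), chosen after their values were seen, also rose as deposited, but Krt6a missed the threshold after centring (limma adjusted p = 0.0622) and in 12 alternatives in all. Sprr2i missed it in 5 alternatives and Gm5416 in 2. One of the 21, and of the 16, Gm5414 (1.96 ± 0.14), chosen after its values were seen, read the same value, 4.42, on all 4 KO arrays, for a reason not known here. The list of EGFR ligands, their receptors and ADAM proteases had 4 of 13 genes named, too few to test. All 4 were ligands and rose, namely Ereg (8.03-fold, SE 0.60 on the log2 scale), Epgn, Areg (2.46 ± 0.36) and Hbegf (1.71 ± 0.42), the last of which missed the threshold in 2 alternatives. A second Ereg probe set gave 1.71, and 1 WT value of Ereg, 8.75, lay within the KO range. The wound list's call was lost without KO replicates 1, 2 or 4 (adjusted p = 0.117, 0.1 and 0.173, exact tests) and without WT replicates 1, 2, 3 or 4 (0.166, 0.105, 0.162 and 0.064, exact tests). It was also lost with low probe sets left out (0.249), without moderation (0.318) and without both arrays that stood apart (0.0613), all by the exact test.

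**Figure D2:**
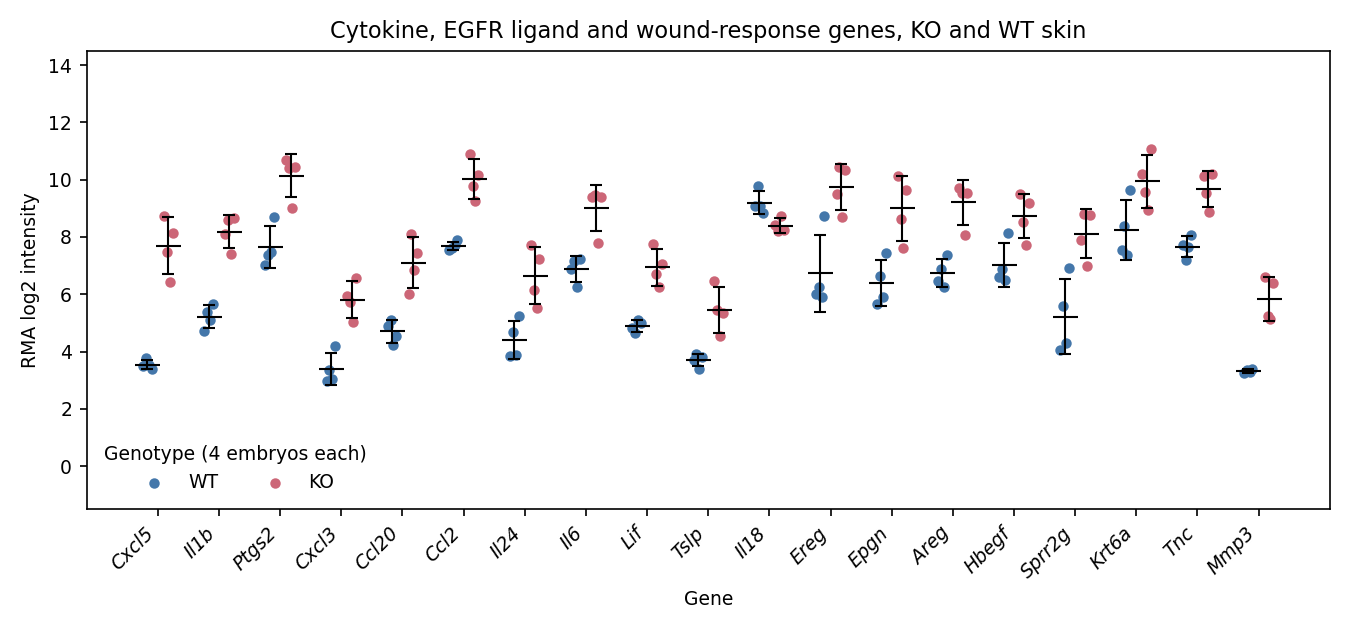
RMA log2 intensity (y axis) of cytokine, EGFR ligand and wound-response genes (x axis) in each of 4 WT and 4 KO embryos, with points for embryos and bars for the mean ± SD. Cxcl5 averages 7.70 in KO and 3.55 in WT skin, and Il18 is the gene drawn that lies lower in KO skin.

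Signalling and stress lists held mostly rises among their named genes, without a direction that set them apart from other named genes. All 10 named NF-kB feedback genes of 20 rose (adjusted p = 0.255, Fisher's exact test), among them Tnfaip2 (1.47 ± 0.19, SE) and Nfkb1 (1.28 ± 0.27). All 13 named immediate early genes of 30 rose (adjusted p = 0.117, same exact test), led by Arc (2.38 ± 0.52), Fosl1 (2.01 ± 0.45) and Dusp6 (1.67 ± 0.30). In the type 2 cytokine list 9 of 22 rose and 1 fell (adjusted p = 0.704, same exact test). The cytokine Tslp (1.75 ± 0.32) and the receptor Il4ra (1.19 ± 0.20) rose, and the transcription factor Gata3 (−0.90 ± 0.11), chosen after its value was seen, fell. Among 35 interferon response genes 10 rose and 2 fell (adjusted p = 0.779, same exact test), with Cxcl9 at 1.66 ± 0.20 and Iigp1 at 1.04 ± 0.23. The 2 that fell, chosen after their values were seen, were Irf1 (−0.90) and Oas1a (−0.59), which missed the threshold in 3 alternatives. All 7 named oxidative stress targets of NRF2, of 37, rose (adjusted p = 0.529, same exact test), with Akr1c18 at 1.59 ± 0.39, which missed the threshold in 2 alternatives, and Sqstm1 at 1.06 ± 0.17. Among 27 antimicrobial genes 6 rose and 1 fell (adjusted p = 0.779, same exact test). S100a9 rose by 1.19 ± 0.27, and its partner S100a8 (1.24 ± 0.37) missed the threshold after centring and in 11 alternatives in all. In the heat shock and unfolded protein list 6 rose and 1 fell of 26 (adjusted p = 0.779, same exact test). The chaperone gene Dnajb9 rose (1.37 ± 0.30) and Ddit4 fell (−0.83 ± 0.15). In the hypoxia and glycolysis list 4 of 29 genes were named, too few to test, and all 4 fell as deposited, namely Egln3 (−0.76 ± 0.14), Ldha (−0.64 ± 0.12), Slc2a1 (−0.54 ± 0.13) and Pdk1 (−0.50 ± 0.16). Pdk1 missed the threshold in 9 alternatives, among them the replicate block, and Slc2a1 without both arrays that stood apart. Of 24 glucocorticoid, vitamin D and calcium genes 8 rose and 1 fell (adjusted p = 0.704, same exact test), with the ion channels Trpv3 (1.54 ± 0.28) and Orai1 (1.01 ± 0.18) in front. Of 16 clock genes 4 rose and 2 fell (adjusted p = 0.779, same exact test), with Ciart at −1.03 ± 0.13 and Nr1d2 at 0.83 ± 0.15.

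**Figure D3:**
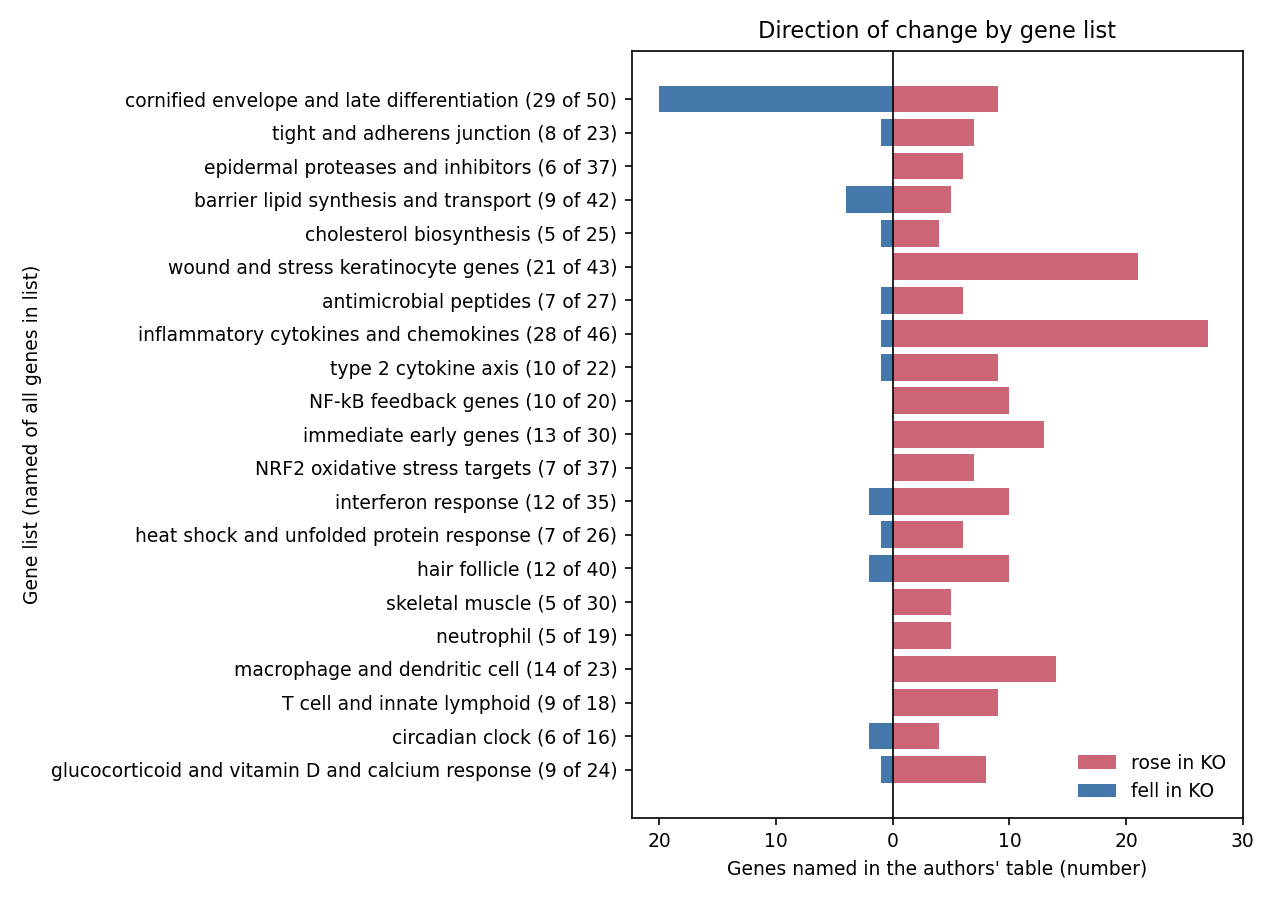
Number of genes (x axis) that rose, to the right, or fell, to the left, in KO skin in each of the 21 tested gene lists (y axis), among the genes named in the authors' table. The cornified envelope list holds 20 falls and 9 rises, and the cytokine list 27 rises and 1 fall.

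None of the tested lists of other cell types passed the direction test. Of 38 cell cycle genes 1 was named, Birc5 (−0.65 ± 0.16, SE). All 4 named basal keratinocyte genes of 21 rose, led by Pdpn (1.21 ± 0.18), and 2 of them passed after centring. Of 40 hair follicle genes 10 rose and 2 fell (adjusted p = 0.779, Fisher's exact test), with the inner root sheath keratins Krt72 (1.59 ± 0.24) and Krt25 (1.20 ± 0.31) in front; Krt25 missed the threshold in 5 alternatives. All 5 named muscle genes of 30 rose (adjusted p = 0.611, same exact test), with Myh1 at 1.28 ± 0.20, and 2 of them passed after centring. All 3 named fibroblast genes of 27 rose as deposited, with Mfap5 at 0.78 ± 0.23, but 0 passed after centring. The same was true of the 1 adipocyte gene of 19, Cidea (0.80 ± 0.25), and of the 2 endothelial and pericyte genes of 19, Rgs5 (0.64 ± 0.17) and Cldn5 (0.55 ± 0.15). Mcpt4 (0.78 ± 0.15) was the 1 mast cell gene named of 13, and the nerve list had too few named genes to be tested. The 2 melanocyte genes of 10, Slc45a2 (0.72 ± 0.14) and Mlana (0.70 ± 0.19), rose, though Mlana missed the threshold in 7 alternatives. Of 16 erythroid genes 3 rose as deposited, among them Hbb-bt (0.85 ± 0.15), and 1 of the 3 passed after centring. All 4 named WNT, BMP and SHH genes of 24 rose, with Bmp4 at 0.74 ± 0.14, and 2 of them passed after centring. In the list of Y-linked genes and Xist 0 of 5 genes were named. The authors' deposited table holds 7 probe sets on chromosome Y, of which 2 rose and 5 fell, with group means of 1.92 to 5.36. None carries a symbol of that list, but some carry no symbol and could belong to it. One of them, chosen after its value was seen, was the sex-determining gene Sry (−1.40 ± 0.15), and the sexes of the embryos are not known. All genes given a change here had an adjusted p under 0.05 in limma with the values as deposited.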

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

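The check for single values far from their group was applied to the named genes only after their changes had been seen. Of 250 groups of 4 values, 16 held a lowest or highest value whose gap to the nearest of the others exceeded Dixon's 95% critical value as a share of the range. Chance flags about 1 in 20 groups, which would be 12.5 here.

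KO replicate 3 held 4 of these values, each the lowest of its group in log2 intensity. They were Fgf23 at 6.50 (others 8.21 to 8.52), Ptgs2 at 9.01 (others up to 10.68), Areg at 8.05 (9.54 to 9.69) and Sfn at 7.27 (7.89 to 8.01). WT replicate 4 held 5. Arc at 7.61 (others 5.86 to 6.05) and Ereg at 8.75 (5.91 to 6.27) were the highest of their group there, and Birc5 at 5.82 (6.17 to 6.19), Rgs5 at 8.62 (9.20 to 9.30) and Slc45a2 at 5.54 (6.00 to 6.09) the lowest. KO replicate 4 held 3, namely S100a8 at 6.54 (others 4.90 to 5.08) and Mmp9 at 5.31 (4.83 to 4.86) as the highest and Hbb-bt at 4.21 (4.64 to 4.68) as the lowest. Krt73 was lowest in KO replicate 1 at 8.24 (others 8.93 to 8.99). Lce6a was highest in WT replicate 2 at 8.82 (8.22 to 8.24), Isg15 lowest in WT replicate 3 at 4.28 (4.96 to 5.06), and Ldha lowest in WT replicate 1 at 6.92, a gap of small size from the others at 6.94.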

How the results depend on the processing

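Cyclic loess, counting identical probe sets singly, leaving out both arrays that stood apart, leaving out the Lce1 genes from the list tests, and the authors' criteria were chosen after seeing the data. The fall of Cdsn kept its call in all 18 alternatives. Of the 121 other named genes, 72 kept theirs in every alternative that tested them. Among results of single genes, 263 missed the threshold and none changed sign. The lack of sign changes cannot be read as a check. These genes were named because their changes in the same values met the authors' criteria, and some alternatives, such as no moderation, leave the change itself as it was. As deposited, 7194 probe sets changed, 5138 higher and 2056 lower. With probe sets under the median level left out, fewer were tested, and 3299 changed (2420 higher, 879 lower). Requiring a 1.5-fold change gave 4171 (3058 and 1113), and with an unadjusted p 4609 (3348 and 1261). Centring gave 2965 higher (49.1% rises), quantile normalization 3229 higher and 3169 lower (50.5%), and cyclic loess 3227 and 3165 (50.5%), since each removes the offset between the arrays. Leaving out each array gave 4821 to 6424 changed, 3486 to 4604 higher and 1335 to 1820 lower, with fewer arrays behind each test, the lowest count without WT replicate 3. Without both arrays that stood apart 5060 changed, 1358 of them lower. Lists with a direction of their own numbered 3 as deposited, 1 with low probe sets left out, 1 without both arrays, and 1 to 3 with each array left out; the cause was not tested. The envelope list kept its call in 18 of 19 and lost it with the Lce1 genes left out (adjusted p = 0.58, exact test), where 2 lists passed. In every alternative the list tests used only genes named from the values as deposited. Genes that passed only in an alternative had no name and could not enter, so these list tests are not independent checks. With the replicate number as a block, 6250 changed, 5795 of them with the same sign and call. The numbers were not taken to pair the embryos: deviations of same-numbered arrays from their group means correlated at −0.03, 0.14, 0.23 and 0.01, and 4 of 8 arrays correlated best with their own number. Not run were camera (also with an estimated correlation or on ranks) and fry, which need names of unchanged genes, Xist as a covariate, 1 probe set per gene, and the authors' table as a source of values, which holds no value per array. No background value was used here, so low signals could not be judged against background.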

Other observations

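The test of other splits and the test of the share of changed genes around Cdsn were laid down before their results were seen. All other tests here, and the families and genes named, were chosen after the results were seen.

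Of 23 gene families defined by their symbols, 8 differed from the other named genes in their share of rises (Fisher's exact test, Benjamini-Hochberg adjusted), among them the Lce1 genes. The families were picked after the values were seen, so these p-values describe them and add no independent evidence. All 15 named small nucleolar RNA genes fell (median −0.77, adjusted p = 3.57e-08, exact test). All 15 also passed the threshold after centring, but centring lowers every KO minus WT change and so enlarges falls. Examples are Snord70 (−0.82 ± 0.17, SE) and Snora62 (−0.62 ± 0.17), the latter missing the threshold in 5 alternatives. Of 25 genes of CD antigens 24 rose (adjusted p = 0.0381, exact test), and of 54 solute carrier genes 48 rose (adjusted p = 0.0384, exact test). After centring, 19 of the 25 and 42 of the 54 passed the threshold. Of these families, 7 CD antigen genes and 2 solute carrier genes were also in the fixed lists. Besides the Lce1 and small nucleolar RNA genes, 4 families had a smaller share of rises than other named genes. They were the microRNA genes (41 of 71 rose, adjusted p = 0.0195, exact test), the T cell receptor alpha variable genes (6 of 15, 0.0314, exact test), the vomeronasal receptor genes (20 of 37, 0.037, exact test) and the olfactory receptor genes (111 of 169, 0.045, exact test). The median WT level was 2.76 for the olfactory and 2.61 for the vomeronasal receptor genes. Of the calls at a mean level up to 3, 697 were rises and 386 falls. At levels of 8 to 10, 542 were rises and 89 falls. The share of rises among the olfactory receptor genes was close to that of calls up to level 3. It therefore does not set them apart from probe sets of like level. Calls were more frequent below the median level of all probe sets (24.2% of probe sets) than above it (18.4%).

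Single genes outside the lists also changed (limma, adjusted p under 0.05). Xrcc2, a DNA repair gene, rose by 2.25 ± 0.37 (SE), and Mdm2, a regulator of p53, by 1.88 ± 0.37. The epithelial interferon gene Ifnk rose by 2.01 ± 0.45, the simple-epithelium keratin Krt18 by 1.94 ± 0.40, and Tnfaip6 by 1.86 ± 0.20; Ifnk and Krt18 missed the threshold without moderation (adjusted p = 0.0723 and 0.0551). The chemokine receptor gene Ccr4 fell (−1.51 ± 0.17).

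The number of changed probe sets, 7194, was reached by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one. The highest of the others gave 1. A rank of 1 in 35 is the best this test can give, so it does not exclude chance. The other splits mix the genotypes, so the difference between genotypes adds to their spread and lowers their counts. The excess of rises is another matter. After centring, 49.09% of calls were rises, but centring brings the balance near even whatever the cause of the shift. An offset in scale between the arrays and a real shift of many transcripts therefore cannot be told apart, and the sources used do not state whether the 8 arrays were scaled together. Such an offset does not account for the calls as a whole, since 69.79% of them kept sign and call after centring.

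The fall of the Lce1 genes has several candidate explanations. The 11 Lce1 probe sets of class 1 fell by a median of −2.162, and the smallest fall among them was −1.38. All 14 Lce1 genes of the fixed list were named, so the fall was not confined to the 3 of class 3. This cannot decide whether probes shared between copies made the members fall together, since binding between copies was not measured. As to a loss of the uppermost layers with the tape, 6 other late-differentiation genes were named outside the Lce and Sprr families. Flg, Flg2, Lor, Hrnr and Krt78 fell and Tchhl1 rose. Their changes ranged from −0.953 to 0.647, with a median of −0.616 (median SE 0.125). The Lce1 gene that fell least was at −1.38. Lce6a, left out of these 6, fell by −2.06. Because Lce6a fell as the Lce1 genes did and unchanged genes were not named, these values cannot decide for or against such a loss. A response of the Lce1 genes to the lack of corneodesmosin stays open as a hypothesis. A partial or whole loss of upper layers and a part of shared probes stay open too.

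Changed genes were dense around Cdsn. Of the 100 nearest coding genes in RefSeq, 25 were named as changed (20 rose, 5 fell), against a median of 15 over like windows, at the 97.49 percentile. The neighbour 2300002M23Rik rose (1.34 ± 0.16, SE), and Psors1c2 (0.78 ± 0.24) rose as deposited but missed the threshold after centring (limma adjusted p = 0.0627). Gm9573 (−1.04 ± 0.12), also close to Cdsn, and H2-M10.4 (−1.75 ± 0.12) fell. With immune genes left out of every window the share fell to the 81.27 percentile, with 19 genes named as changed against a median of 15. Immune genes of the histocompatibility region, which holds Cdsn, may therefore account for part of the density. A segment of another strain carried along with the floxed allele cannot be told apart from this, since such a segment would hold the same genes and no sequence was measured.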
